A study of Anas platyrhynchos with 2 samples.

How the data were processed

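RNA of the Fujian Longyan Shan-ma duck, a breed of Anas platyrhynchos, was sequenced in 2 libraries for a near-complete genome assembly. RNA was extracted with an RNeasy kit and libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. The library whose label lists blood, stomach, intestine, liver and pancreas is called library A. The library whose label lists brain, eye, heart, lung, kidney, spleen, muscle, ovary and skin is called library B. The labels therefore name 5 and 9 organs with none in common. The series text describes instead a female and a male donor, testis taking the place of ovary in the male, and equal amounts of RNA from all tissues combined. The labels mention neither a testis nor the sex of the donor, so values are given for "library A" and "library B" and not for organs or sexes. The alignment named in each count file's header does not carry the library name that the labels give, so the assignment of counts to labels rests on the deposit's own pairing of files with samples.

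The deposited values are raw counts of reads per gene, made with featureCounts 2.1.1 per the file headers. Reads were summed over the exons of each gene of the study's own annotation, in paired-end mode, per the same headers. The recorded command has no option for strand, for counting read pairs, for multi-mapping reads or for reads that overlap several genes. With these settings the mates of a pair are counted separately, strand is ignored, and reads that map to several places are not counted. HISAT2 and SAMtools are named without versions in the submitters' processing notes. The name of the genome build, the trimming and the alignment settings are not given in the sources used here. Coordinates are on the study's own assembly, as the count files name its sequences.

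Each count table held 11383 genes, and the length of each gene equalled the summed length of its exons in all 11383. Their IDs are numbered in steps of 10, and 11383 of the 18306 numbers up to the highest of each sequence (62.2%) are in the table. Genes under other numbers, if any, were not analysed here, so library totals, shares of reads, CPM and gene density refer to the genes in the table. No gene spans in the table overlapped. Gene IDs were compared with a reference table of 26024 duck genes and matched 0 of them. The 21 lists of organ markers and reference genes fixed before the data were examined were therefore not evaluated, and genes appear under the IDs of the files.

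Library A held 20047449 counted reads and library B 41792653. A count of 0 allows up to 3 counts, which is 0.15 CPM (counts scaled to a common library total) in library A and 0.0718 in library B. Intervals and this floor cover counting error only, because reads without molecular identifiers are not independent molecules. Since mates were counted separately, intervals from reads are too narrow and this floor is too low. Intervals from counts halved to read pairs are given beside those of named genes. Among genes with at least 1 and fewer than 50 reads, 59.5% of 716 had an even count in library A and 58.9% of 370 in library B. After random thinning of library B, which separates mates, the share was 50.5% of 705.

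With 1 library per label no model across replicates can be fitted, so no p-value, standard error or call of change is given. Counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 0.997 and 1.003. The log2 ratio of library B over library A used a prior count of 2, for the 11256 genes with at least 10 reads in at least 1 library. A size rule of 4-fold was set before the data were examined. Ratios of named genes carry exact conditional binomial 95% intervals, shares of reads Clopper-Pearson 95% intervals, and medians over genes bootstrap 95% intervals. Gene level means RPKM, that is CPM per kilobase of exon, computed here from the counts and averaged over both libraries. The similarity of the libraries was described by correlations of log2 CPM across genes, with a pseudocount of 0.5 CPM, and by a chi-square statistic per gene.

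The rule for named genes, also set beforehand, allowed 2 IDs per library for the most abundant genes and 2 IDs in each direction. The latter had the largest ratios among genes with at least 100 reads in the higher library. Other genes are given by position and were chosen after their values were seen. Chromosome size classes, the ratios of sex chromosomes to autosomes, gene clusters and the relation of ratio to chromosome span were also chosen after the values were seen.

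The procedure was tested on simulated counts for 11260 genes. Genes to be changed were drawn from those with at least 100 reads over both libraries, so recovery of genes with fewer reads was not tested. All 100 genes simulated 8-fold apart passed the 4-fold rule. Of 100 genes simulated 2-fold apart, 0% passed the 4-fold rule and 49% passed a 2-fold rule. Of 11060 unchanged genes, 12 passed the 4-fold rule (0.108%) and 0.542% the 2-fold rule. Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, other filters, another prior count, other size rules and thinning of library B. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.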

Results

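The transcriptome of the Fujian Longyan Shan-ma duck was sequenced to accompany an assembly of its genome. Expression was measured in 2 RNA-seq libraries, 1 per label, with no replicates. Library A was labelled blood, stomach, intestine, liver and pancreas, and library B was labelled brain, eye, heart, lung, kidney, spleen, muscle, ovary and skin. Library A held 20047449 counted reads and library B 41792653, a ratio of 2.08. The median gene had 706 reads in library A and 1496 in library B.

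Nearly every gene in the count table had reads in both libraries. The table holds 62.2% of the ID numbers up to the highest of each sequence, and shares of reads refer to its genes. The transcriptome was sequenced to improve the annotation of the genome, and whether genes entered the table because of these reads is not known. The share of genes with reads may therefore be high by construction. Of 11383 genes, 11312 had at least 1 read in library A and 11345 in library B. At least 10 reads were counted for 11161 genes in library A and for 11245 in library B. Library B, thinned at random to 20048896 reads, had 11168 such genes. No read was counted in either library for 31 genes (0.272%), which does not show that these genes are silent at greater depth.

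Genes with many exons had more reads and were seldom without any. The 2450 genes with at least 17 exons had a median of 49.3 CPM in both libraries, and none of them lacked reads. Genes with 2 exons had medians of 11.3 CPM in library A and 12.3 CPM in library B. The 148 single-exon genes had medians of 6.78 and 6.40 CPM. Of these single-exon genes, 2.70% had no read in either library and 10.8% had fewer than 10 reads over both. Counts per gene rise with exon length, and the level per kilobase did not follow the same order. It was 2.67 RPKM for single-exon genes, 11.7 RPKM for genes with 5 to 8 exons and 8.36 RPKM for genes with at least 17 exons, below the 9.40 RPKM of all genes. Of the 2278 shortest genes, with 273 to 1747 bp of exon, 1.05% had no reads, against 0% of the 2277 longest, with 5722 to 33507 bp. The median level was 17.5 RPKM in the shortest and 6.39 RPKM in the longest of these groups.

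A small number of genes accounted for much of each library. The most abundant gene in both was Apl_2G0006690, at 79899466 to 79907284 on the minus strand of chromosome 2, with 8 exons and 2085 bp of exon. It took 8.13% of reads in library A (95% interval 8.12 to 8.14) and 8.06% in library B (8.05 to 8.07). It shared its inner exon lengths with another gene in the table, and reads that map to several places were not counted. Sequence was not compared, so its share may be uncertain beyond these intervals. Next was Apl_14G0001690, at 8699080 to 8705891 on the minus strand of chromosome 14, also with 8 exons, which took 2.72% and 2.59%. The 10 most abundant genes held 16.5% of reads in library A and 16.2% in library B, and they were the same 10 genes in both. The 100 most abundant held 30.03% and 29.68%, with 97 of 100 shared.

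Several of the most abundant genes lay side by side, a feature chosen after the values were seen. On chromosome 2, 3 genes of 8 exons each with consecutive IDs, between 79899466 and 79938395, a stretch of 38.9 kb, ranked 1, 7 and 9. Together they held 9.05% of reads in library A and 8.96% in library B. The next gene, starting at 79942722, had 0.751 CPM in library A and 0.525 CPM in library B. On chromosome 14, 2 genes with consecutive IDs between 8699080 and 8726891 ranked 2 and 8 and held 3.21% and 3.06% of reads.

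The comparison implied by the labels is between the organs of library A and those of library B. Expression was nearly proportional between the libraries. Over 11256 genes the median log2 ratio was -0.00066 with a median absolute deviation, scaled to the SD of a normal distribution, of 0.11, and 85 genes (0.755%) were at least 2-fold apart. Among the 100 most abundant genes the log2 ratio ran from -0.09 to 0.45. The correlation of log2 CPM across genes was 0.996 (Pearson, bootstrap interval 0.9957 to 0.9964) and 0.997 (Spearman), where genes are not independent replicates. The libraries nevertheless differed by more than sampling noise, with a mean chi-square per gene of 2.12 in read pairs, where sampling alone gives about 1. In reads it was 4.24, which overstates the excess because mates were counted separately. In read pairs the mean was 6.31 among the 1126 most abundant genes. The median over all genes was 1.46 times its expected value.

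**Figure D1:**
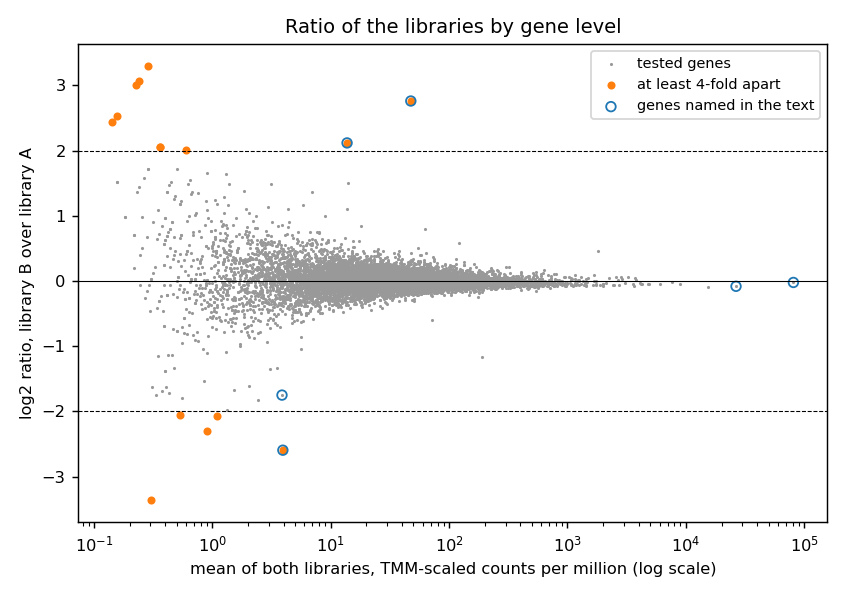
Log2 ratio of library B over library A (vertical axis) against the mean TMM-scaled CPM of both libraries (horizontal log axis) for 11256 genes, 1 point per gene. Dashed lines mark 4-fold, orange points are the 15 genes beyond it, and blue rings are genes named by ID in the text.

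Few genes differed widely between the libraries. By the 4-fold rule 10 genes were higher in library B and 5 in library A, and 5 of the 10 and 1 of the 5 had no reads in the other library. In 100 simulated pairs of libraries that differed by counting of read pairs alone, a median of 7 genes and at most 16 passed the rule, so counting alone reached the total of 15. The largest ratio among genes with at least 100 reads was that of Apl_U0002810, on the minus strand of contig ptg000119l at 28144 to 31881, with 7 exons. It had 12.2 CPM in library A and 82.8 CPM in library B, 6.81-fold higher (5.97 to 7.78 from reads, 5.64 to 8.21 from read pairs). Apl_8G0002590, on the plus strand of chromosome 8 at 18795770 to 18818397, with 4 exons, was 4.38-fold higher in library B (3.57 to 5.43, and 3.28 to 5.97 from pairs). In the other direction, Apl_U0003370, on contig ptg000129l at 102543 to 106604, with 9 exons, had 136 reads in library A and 45 in library B. It was 6.34-fold higher in library A (4.50 to 9.10, and 3.96 to 11.02 from pairs). Apl_U0001450, on contig ptg000075l at 123531 to 133767, with 5 exons, was 3.45-fold higher in library A (2.56 to 4.68, and 2.28 to 5.44 from pairs) and so did not reach the 4-fold rule. Each of these 4 genes shared its inner exon lengths with another gene in the table. Sequence was not compared, so whether similar copies affected their counts, and with them the ratios, is not known. These differences have no replicate check, and the counts at 4-fold fell to 2 and 1 when at least 50 reads were required. With library B thinned, 3 genes were higher in library B and 7 in library A, so the larger number in library B did not hold there. No spread over repeated random draws is given for these small counts.

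Among genes with more reads, chosen after their values were seen, 1 with 8 exons on chromosome 5 at 30047478 to 30051966 had 260 CPM in library A and 116 CPM in library B, 2.25-fold higher in library A. A gene with 2 exons on chromosome 38 at 7087688 to 7095195 had 1527 CPM in library A and 2090 CPM in library B. This 1.37-fold ratio was the widest among the 100 most abundant genes.

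Large chromosomes contributed to the libraries in nearly equal shares, and some small sequences did not. The autosomes spanning over 30 Mb, with 5645 genes, held 53.4% of reads in library A and 53.1% in library B. Autosomes of 10 to 30 Mb held 29.995% and 30.001%, and those under 10 Mb held 12.4% and 12.6%. Unplaced contigs held 0.966% in library A and 1.05% in library B, chromosome 33 held 0.261% and 0.288%, and chromosome 38, which carries the abundant gene with 2 exons given above, held 0.224% and 0.286%. Chromosome 2 held 16.5% and 16.4% of reads with 9.19% of the genes, and it carries the abundant cluster described above. The median gene level was 8.97 RPKM in the class over 30 Mb, 10.6 RPKM in that of 10 to 30 Mb and 10.2 RPKM in that under 10 Mb.

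Small chromosomes differed widely in how many genes they had in the table. Chromosome 34 had 47.4 genes per Mb in the table and chromosome 31 had 0.625. The 8 autosomes under 10 Mb with fewer than 10 such genes per Mb, with 188 genes, had a median level of 2.91 RPKM, against 11.1 RPKM for the 1423 genes of the 8 denser ones. Chromosome 30, within the sparser set, had 7.22 RPKM, and chromosome 33, just above the size limit with 7.25 genes per Mb, had 9.09 RPKM. The table holds 18.6% of the ID numbers of the sparser set and 63.3% of those of the denser set, so neither density nor level describes all genes that may lie there.

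**Figure D2:**
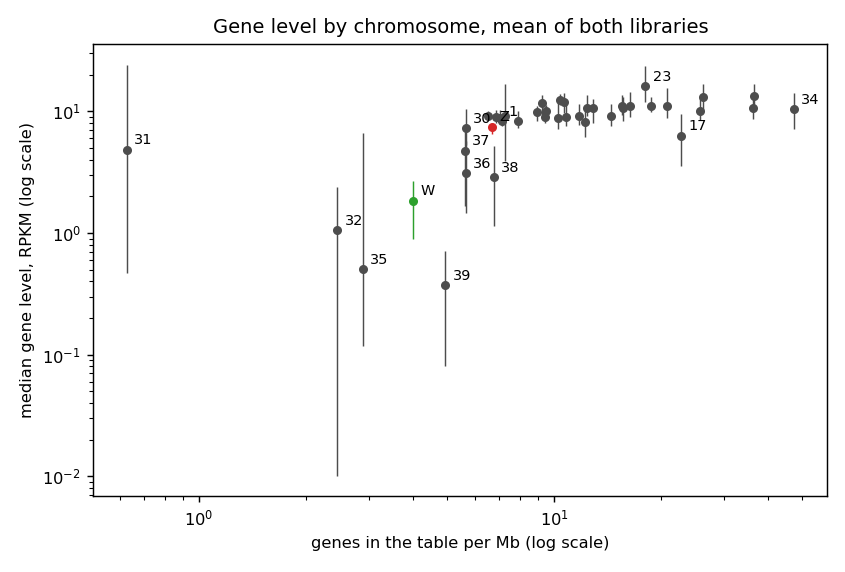
Median gene level in RPKM (vertical log axis, mean of both libraries, bars are bootstrap 95% intervals over genes) against genes per Mb (horizontal log axis, genes in the table), 1 point per chromosome with at least 5 genes, with Z in red and W in green. Chromosomes 39, 35 and 32 lie lowest, at 0.372, 0.505 and 1.05 RPKM, followed by W at 1.84 RPKM.

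The ratio of the libraries shifted slightly with chromosome size. The median log2 ratio was -0.01 (-0.015 to -0.008) on autosomes over 30 Mb, 0.04 (0.033 to 0.047) on those under 10 Mb and 0.11 (0.096 to 0.137) on 33 unplaced contigs. Chromosome 30 had the highest median among chromosomes with at least 20 tested genes, 0.19 (0.06 to 0.27). Autosomes 31, 32, 35 and 39 had fewer than 20 tested genes, with medians of 0.130, -0.008, 0.010 and -0.061 and wide intervals. Without them, over the other 35 autosomes, Spearman's rho between span and median log2 ratio was -0.88. It was -0.88 when chromosomes 1 and 30 were also left out. The chromosomes of 2 libraries are not replicates, so no p-value is given for this 1 relation.

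**Figure D3:**
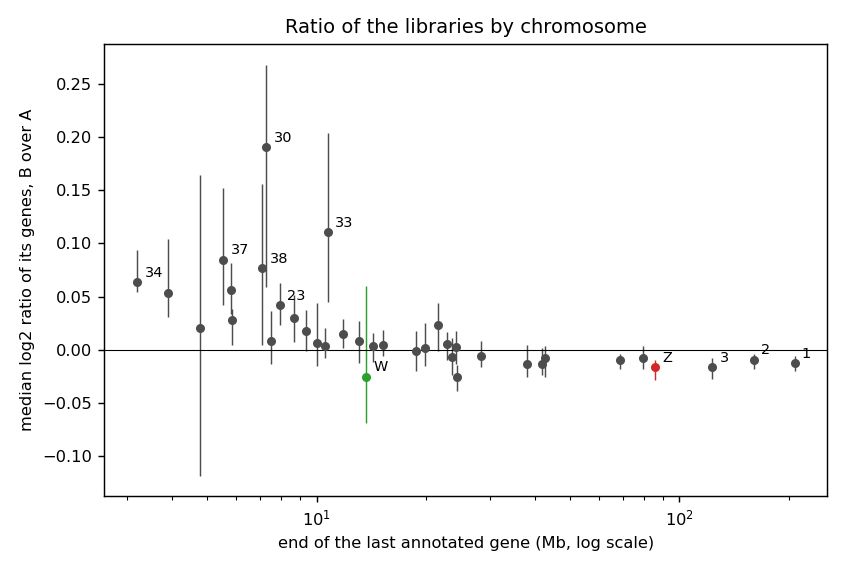
Median log2 ratio of library B over library A for the genes of each chromosome (vertical axis, bars are bootstrap 95% intervals over genes) against the end of its last annotated gene in Mb (horizontal log axis), for chromosomes with at least 20 tested genes. Z is red and W is green, and chromosome 30 lies highest at 0.19.

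Birds carry Z and W sex chromosomes, with females ZW and males ZZ. Chromosome W, which males lack, contributed a like share of reads to both libraries. The 55 W genes held 0.121% of reads in library A and 0.120% in library B, a ratio of 0.998 (0.976 to 1.02, from read pairs), and none of them had 0 reads in either library. The 37 W genes with at least 100 reads had log2 ratios from -0.49 to 0.46. Of 48 tested W genes 3 (6.25%) were at least 2-fold higher in library A, with at most 14 reads in library A and 8 in library B, and all 3 lay in the array described next. The median level of all 55 W genes was 1.84 RPKM, 0.191 times that of autosomal genes (0.0906 to 0.277). The share of male RNA is not known, so this ratio does not give the level of W genes in females. An array of 15 W genes at 13134375 to 13570782, 14 of them with 3 exons, had a median of 0.623 RPKM, against 2.26 RPKM for the other 40. Array members resemble each other in structure, and sequence was not compared, so their counts may be uncertain.

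Chromosome Z, with 573 genes, held 3.17% of reads in library A and 3.14% in library B. Its median level was 7.45 RPKM against 9.66 RPKM for 10552 autosomal genes, a ratio of 0.771 (0.667 to 0.846). The ratio was 0.761 in library A and 0.771 in library B. Along Z, in steps of 20 Mb, the median level was 7.26, 7.57, 7.64 and 7.88 RPKM, and 4.94 RPKM over the last 36 genes.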

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

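The recount in read pairs, the omission of unplaced contigs and the minimum of 100 reads were chosen only after the results were seen. Of 80 alternatives 61 left the value within its interval or within 1.5 times the count, 19 moved it and 0 reversed its direction. Each value was taken alone here, not the balance of the counts of the 2 libraries. The number of genes 4-fold higher in library B was 10, and it stayed at 10 under each of the other 3 scalings. It became 2 with at least 50 reads, 55 with a 2-fold rule, 3 with an 8-fold rule, 1 by the nearer bound of the counting interval and 3 with library B thinned. The number higher in library A was 5, and became 1 with at least 50 reads, 30 with a 2-fold rule, 1 with an 8-fold rule, 2 by the nearer bound and 3 without unplaced contigs. With library B thinned it was 7, given without a spread over repeated draws. Library A thus had more such genes than library B after thinning and by the nearer bound, the reverse of the main result. Fewer genes qualify under a stricter filter or rule by construction, and the counts at 4-fold rest mainly on genes with few or no reads in the lower library. The correlation was 0.9957 without the 100 most abundant genes, and the cause was not tested. The chi-square per gene was 2.12 in read pairs, which halving the counts gives by construction. Genes with fewer than 10 reads over both libraries made up 0.896%, against 0.272% without reads. With total counts the median log2 ratio was -0.0063 for Z and 0.0481 for autosomes under 10 Mb, because 1 factor shifts all genes. For the named genes 20 of 24 alternatives left the ratio within its interval, and the others moved the 2 most abundant genes, whose intervals are very narrow. Alternatives for the marker lists were not run because no ID matched a symbol, and neither was the share without mitochondrial and ribosomal RNA genes, which the files do not name. No paired analysis was possible because each label names 1 library. Depth limits genes with few reads: among the 1126 genes of the lowest level, at a median of 2.18 CPM, the median absolute deviation of the log2 ratio, scaled to the SD of a normal distribution, was 0.42, against 0.055 among the 1126 of the highest level, at 238 CPM.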

Other observations

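Tests in this part were chosen after the results had been seen, except those whose predictions were written before their values were seen. The exceptions were structurally alike genes among all genes at least 2-fold apart, and Z against autosomal genes matched on length and exon number. A further exception was adjacent genes, whatever their gap or strand, against shuffles.

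Neighbouring genes had slightly similar levels. The rank correlation of level between genes adjacent in the table was 0.106 over 11309 pairs, above the highest of 1000 shuffles within chromosomes, 0.0632. Without genes that share exon lengths with another gene it was 0.0901 over 10829 pairs, above the highest of 1000 shuffles within chromosomes, 0.0575, so a chance arrangement does not account for it. For the 7995 of these pairs with consecutive IDs it was 0.0852 (0.0616 to 0.109). For 5882 pairs at least 10 kb apart it was 0.0756, above the highest of 1000 shuffles of those pairs, 0.0671. Among pairs under 1 kb apart, it was 0.192 (0.118 to 0.268, 655 pairs) for genes on the same strand. For divergent pairs it was 0.0522 (-0.041 to 0.147, 406 pairs) and for convergent pairs 0.0114 (-0.090 to 0.115, 403 pairs). Transcripts that run into a neighbouring gene may contribute at short gaps, but would have to extend over 10 kb to account for the distant pairs. Over all 2573 divergent pairs, which cannot run into each other, the value was 0.0606 (0.0199 to 0.103). It lay above the shuffle median of 0.0218 and below the highest shuffle of 0.091. The test therefore decides neither way, and the explanation by transcripts that run into a neighbour stays open. The shuffles were not matched on gene length or exon number, with which the level varied. Whether neighbours alike in these account for the correlation was not tested.

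The libraries were nearly proportional although their labels share no organ. Only 0.133% of tested genes were at least 4-fold apart, which argues against libraries that each hold the organs on their label, since organs such as liver, pancreas, brain and muscle have abundant genes of their own; no marker could be checked by name. A W share ratio of 0.998 argues against female RNA in one library and male RNA in the other, and 58 genes over 5 counting standard deviations in read pairs argue against 1 library sequenced repeatedly and processed alike. A single RNA pool made into separate libraries remains a candidate explanation, with a robust chi-square of 1.46 times sampling noise in read pairs, though it was 2.84 among the 1126 most abundant genes. The share of 0.133% thus speaks against the labelled organs for these counts. Whether the pooling described in the series text applies, and whether each count file belongs to its label, was not settled. Differences in read length or alignment settings between the libraries were not tested.

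There were 85 genes at least 2-fold apart, 17 of them with at least 100 reads in the higher library. Counting error cannot be told apart as a source for most of the 85, since 100 simulated pairs of libraries gave up to 66, but among the 17, where the simulated median was 2 and the highest 5, it is argued against by 9 genes whose 95% interval in read pairs, made simultaneous over all 11256 tested genes, leaves out a ratio of 1. Reads shared between near-identical copies may contribute, though sequence was not compared. Of the 85, 22.4% shared exon lengths with another gene, against a median of 5.88% and at most 15.3% in 10000 lists matched on expression. Among the 17 it was 41.2%, against a median of 5.88% and at most 29.4%, with no prediction written beforehand. These lists were not matched on exon length or number. At least 2-fold apart were 2.42% of tested genes with 273 to 1747 bp of exon and 0.0879% of those with 5722 to 33507 bp. Gene length and exon number can therefore not be told apart here from shared reads. Of the 17, 76.5% lay on autosomes under 10 Mb or on contigs, against a median of 17.6% in matched lists, while over all 85 it was 32.9% against 22.4%; base composition, which was not measured, cannot be told apart here from other properties of these sequences. The values of 0.133% and 0.998 above speak against the labelled organs or opposite sexes for the libraries as a whole, while a smaller difference in the makeup of the RNA at these genes was not tested and stays open.

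Genes on Z had a lower median level than autosomal genes. Gene length and exon number are argued against, since 0.02% of 10000 autosomal lists matched on them had a median as low as 7.45 RPKM. Of 10000 matched lists from autosomes over 30 Mb, 0% had one as low, their lowest being 7.54 RPKM. This argues against low levels of genes on large autosomes in general, in a test added after the first had been seen. Both tests drew genes singly from many chromosomes, so variation between whole chromosomes was not tested. The lowest medians among autosomes over 30 Mb were 8.33 RPKM, on chromosome 1 (7.57 to 8.87) and chromosome 7 (7.23 to 10.07). Both intervals overlap that of Z (6.51 to 8.08). Some smaller autosomes had lower medians than Z, such as 17 and 30 at 6.28 and 7.22 RPKM. Fewer copies of Z in female donors may contribute to the ratio of 0.771, but the share of male RNA is not known, so this cannot be told apart from other causes of low Z expression.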
